A study of Mus musculus with 15 samples.

How the data were processed

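RNA sequencing was reported for 15 libraries of the mouse hepatic stellate cell line JS1, in 4 groups set by construct (XPO4 overexpression or empty vector) and treatment (baseline or TGFβ). Dose and duration of TGFβ are not given in the labels. Per the labels' protocols, RNA was selected with poly(A) beads and made into strand-specific libraries with the dUTP method. Per the submitters' processing notes, CASAVA 1.8.2 and STAR 2.7.2b were used, and the genome builds mm10 and GRCh38 are listed with no role given for either. The program that computed the expression values is not given in the sources used here. The deposited values are FPKM, in 1 table for the baseline libraries and 1 for the TGFβ libraries, each with 38277 gene identifiers found in both tables. The values were tested against the unit: FPKM sums of 480030 to 526338 per library and unrounded values fit a length-scaled unit and not counts. Read depth is unknown, so no counting interval is given. Gene positions are from GENCODE M21, which holds 36426 of the 38277 identifiers.

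Groups were taken from the library titles and characteristics. No counts were available, so differences were tested with limma 3.58.1 (with an intensity trend) in R 4.3.3 on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the libraries of a fit were tested, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The effect of overexpression was fitted within each table, on 7 libraries at baseline and 8 with TGFβ. The interaction and the 2 TGFβ effects were fitted on all 15 libraries joined by gene identifier. Xpo4 itself was also tested by an exact two-sided permutation test. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

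The comparisons, the tests, the 30 gene lists and the rule for named genes were set before the data were examined. The lists cover fibrosis and TGFβ signalling, interferon and stress responses, lipid synthesis, growth, nuclear transport, cargo of exportin-4, and markers of other liver cells. Lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation of 0.01, and again with an estimated correlation. They were also tested by fry, which asks whether the members changed in a direction, without comparing them with other genes. A list can thus pass by fry without changing more than other genes. The rule named Xpo4 first. For each comparison it took the 8 largest rises and 8 largest falls among genes that passed, did not overlap between groups and had a symbol that is not a predicted name. Where none passed, it took the 5 genes per side with the smallest p. From each list that passed its set test or held a called gene it took up to 4 members with the smallest p. Smad3, Eif5a, Eif5a2, Acta2, Col1a1, Col1a2, Col3a1, Timp1, Ctgf, Smad7 and Tgfb1 were among those always named, and symbols listed more than once were left out. A few genes that the rule takes are not reported. The text gives a subset of the list members as examples, chosen after their values were seen to favour calls that held with each library left out.

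The tests are unpaired. The tests were also tried on simulated data made from log-scale values with 50 genes changed per fold. At 2-fold, limma recovered 84% and 86% of them for the overexpression effects at baseline and with TGFβ, 66% for the interaction, and 84% and 72% for the TGFβ effects in empty-vector and XPO4 cells. At 1.5-fold the shares were 52%, 40%, 26%, 58% and 56%. Between 3.55% and 6.67% of calls were false. The simulated noise was normal, with each gene's fitted spread, and independent between genes. These shares may therefore not hold for the real libraries, where genes can vary together. Alternatives tried were pseudocounts of 0.1 and 0.5, no filter and a minimum of 5 FPKM, quantile normalization, rescaling to the TPM scale, blocks by replicate number and by library set (2 runs of library codes in the labels, which hold replicates 0 and 1 and replicates 2 and 3; they are not stated to be batches), array weights, limma with no trend, all 4 groups in 1 fit, and leaving out each library in turn. Median centring and a count without the interferon list were added after the data had been seen, and that count is not reported.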

Results

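Gene expression was measured by RNA sequencing in JS1 cells, a mouse hepatic stellate cell line described as TLR4-deficient cells given back wild-type TLR4. Hepatic stellate cells are the liver cells that turn into matrix-producing myofibroblasts in fibrosis. The cells carried an XPO4 overexpression construct or an empty vector, and were left untreated (baseline) or received TGFβ, a cytokine that drives stellate cell activation. There were 15 libraries in 4 groups: 4 empty-vector and 3 XPO4 libraries at baseline, and 4 empty-vector and 4 XPO4 libraries with TGFβ. Within a group the libraries carry the numbers 0 to 3 that the labels give them (0 to 2 for XPO4 at baseline). The series concerns exportin-4 and liver fibrosis, and the design asks what XPO4 overexpression changes without and with TGFβ.

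The values are FPKM for 38277 genes, in 2 separate tables, 1 per treatment. Read depth is unknown because the tables hold no counts. The FPKM of a library summed to between 480030 and 526338, and 11829 to 11971 genes reached 1 FPKM. Replicates are not stated to be separate cultures, so the p-values below measure the spread between these libraries, which may be technical. Changes are differences of log2(FPKM + 1), a scale that understates the change of genes near or under 1 FPKM. Adjusted p-values are from limma with Benjamini-Hochberg correction over all genes tested, and positions are on mm10.

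Xpo4, the overexpressed gene, was about 2-fold higher in the XPO4 cells of both treatments. The gene encodes a nuclear export receptor and lies on chromosome 14 from 57577521 to 57665430. At baseline it measured 15.7 ± 1.69 FPKM (SD, n = 3) with the construct and 7.61 ± 1.44 FPKM (SD, n = 4) with the empty vector, a ratio of 2.06. With TGFβ the values were 14.6 ± 1.42 FPKM and 7.15 ± 1.86 FPKM (SD, n = 4 each), a ratio of 2.04. The XPO4 and empty-vector libraries did not overlap in either treatment. The exact two-sided permutation p was 0.0571 at baseline (n = 3 and 4) and 0.0286 with TGFβ (n = 4 and 4), in each case the smallest that the design allows. In the fit over all genes the log2 change was 0.96 (SE 0.15, limma adjusted p = 0.00669) at baseline and 0.97 (SE 0.17, limma adjusted p = 0.0105) with TGFβ. The baseline call of Xpo4 ended with the replicate number as a block (values in the section on processing). The species of the construct is not stated, and transcripts that map poorly to the mouse gene would not be counted here.

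**Figure D1:**
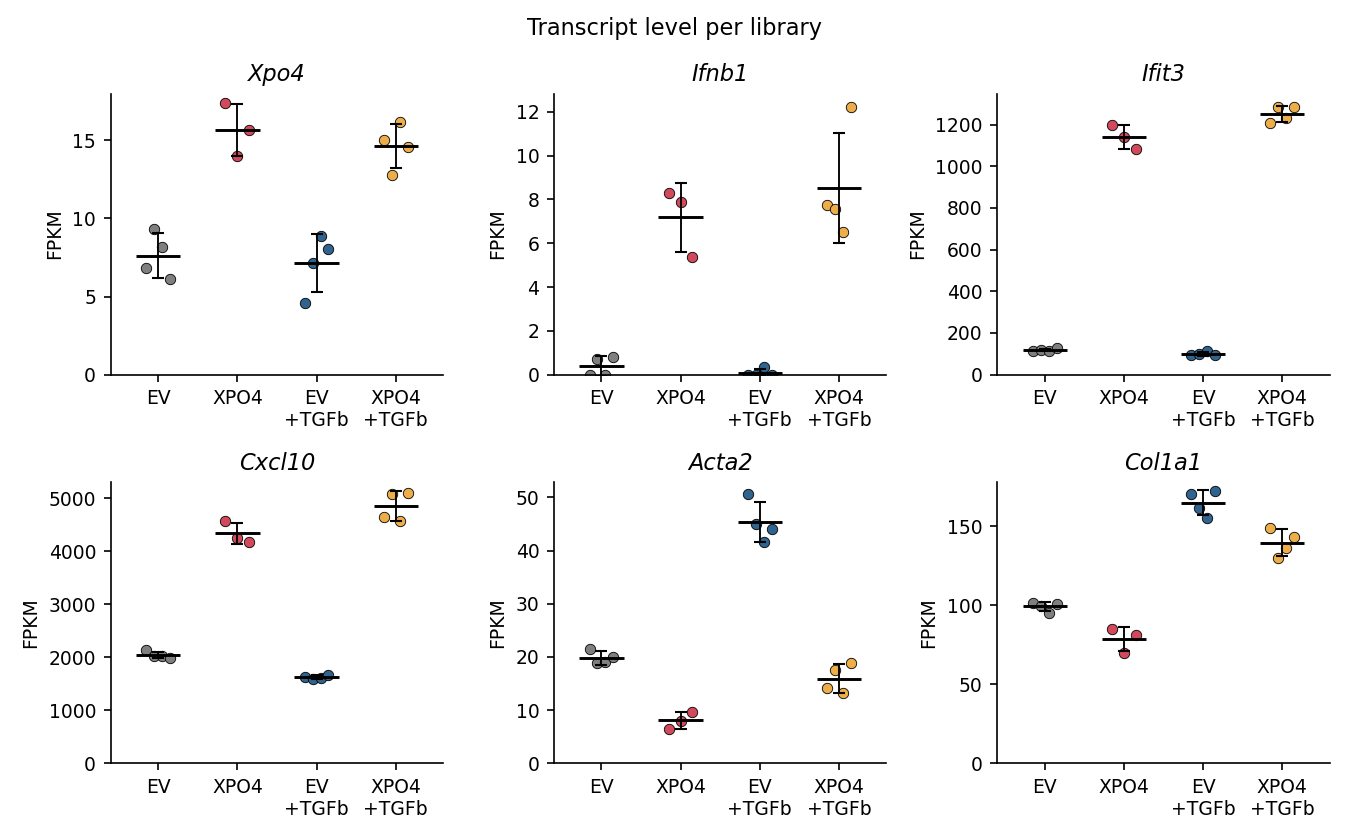
Transcript level in FPKM (vertical axes, from 0) of Xpo4, Ifnb1, Ifit3, Cxcl10, Acta2 and Col1a1 in each library of the 4 groups. Each point is 1 library, horizontal lines are group means and bars are the SD. Xpo4 was 2.06-fold and 2.04-fold higher with the construct, Ifit3 stood at 118 and 1141 FPKM without and with it at baseline, and Acta2 at 19.8 and 8.03 FPKM.

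XPO4 overexpression at baseline came with a broad rise of interferon-stimulated genes. Of the 47 measured members of that list, fixed before the data were examined, 44 rose and 0 fell, with a median log2 change of 1.43. Ifit3, an interferon-induced gene on chromosome 19 (34583531 to 34588731), rose from 118 ± 6.65 to 1141 ± 57.1 FPKM (SD, n = 4 and 3; log2 change 3.26, SE 0.07, limma adjusted p = 1e-07). Mx1, an antiviral GTPase on chromosome 16 (97447035 to 97462907), rose from 2.80 ± 0.54 to 42.5 ± 2.50 FPKM (log2 change 3.53, SE 0.13). Gbp3 and Cmpk2, 2 further members of the list, rose by 2.14 and 2.10. Adjusted over the list alone, 47 members rose. The list passed the set test (camera, adjusted p = 6.86e-90) and also passed it with an estimated correlation (adjusted p = 0.00154).

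Other genes among the 8 largest rises at baseline were Iigp1, an immunity-related GTPase (8.15 to 79.6 FPKM, log2 change 3.16), Tgtp2 (3.32), AI607873 (2.97), Mpeg1, which encodes perforin-2 (1.44 to 15.3 FPKM, 2.75), and Slfn4, a Schlafen family member (2.67). Tgtp2 has a near-identical copy in Tgtp1, and Ifit3 in Ifit3b, so reads could be shared and the level of each copy is uncertain. The gene listed as COX17, which the annotation used here calls Gm21987, was listed at 0 in all 4 empty-vector libraries and at 11.7, 76.2 and 3.27 FPKM in the XPO4 libraries. Its limma adjusted p was 0.0268. The call ended when any empty-vector library was left out (adjusted p = 0.0694, 0.0704, 0.0722 and 0.071 without library 0, 1, 2 and 3) or XPO4 library 0 (0.0815). The rule for named genes takes Ifnb1, the interferon beta gene on chromosome 4 (88522025 to 88522774), with TGFβ; at baseline it falls outside the rule and was chosen after its values were seen. It rose from 0.391 ± 0.453 to 7.18 ± 1.58 FPKM (SD, n = 4 and 3; log2 change 2.60, SE 0.29, limma adjusted p = 0.00085).

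Some chemokine, p53 and stress genes were among those that rose with overexpression at baseline. Of 26 measured NF-κB targets and chemokines, 8 rose and 0 fell (9 and 0 adjusted over the list alone), led by the monocyte chemokines Ccl7 (20.2 to 70.6 FPKM, log2 change 1.76) and Ccl2 (1.60) and the lymphocyte chemokines Cxcl10 (2045 ± 61.6 to 4337 ± 206 FPKM, 1.08) and Ccl5 (1.01). Of 24 p53 targets, 6 rose and 0 fell (13 and 0 adjusted over the list alone), among them the cell cycle inhibitor Cdkn1a (217 ± 14.9 to 360 ± 25.6 FPKM, log2 change 0.73) and Sesn2 (0.65). Of 36 genes of the unfolded protein and integrated stress response, 6 rose and 0 fell (6 and 0 adjusted over the list alone), including the transcription factors Ddit3 (64.2 to 109 FPKM, 0.75) and Atf3 (55.4 to 87.9 FPKM, 0.66). The 3 lists passed camera (adjusted p = 8.56e-09, 2.6e-07 and 0.00395) and lost the call with an estimated correlation (adjusted p = 0.154, 0.139 and 0.343). By fry, which does not compare the members with other genes, they passed (adjusted p = 0.00236, 0.00392 and 0.0347). The count of NF-κB targets was 5 without empty-vector library 1 or 3 or XPO4 library 1 or 2, and 4 without XPO4 library 0. The p53 count was 2 without XPO4 library 0 and 3 without XPO4 library 1, and the stress count was 3 without empty-vector library 1 or XPO4 library 0, 1 or 2.

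Contractile, mesothelial and matrix genes were among those that fell. Acta2, the smooth muscle actin that marks activated stellate cells (chromosome 19, 34241090 to 34255590), fell from 19.8 ± 1.22 to 8.03 ± 1.65 FPKM (SD, n = 4 and 3; log2 change -1.22, SE 0.13, limma adjusted p = 0.00072). Tagln, a smooth muscle protein, fell from 102 ± 10.3 to 61.9 ± 7.57 FPKM (log2 change -0.71). They were the 2 of 21 contractile genes that passed (0 rose; 5 fell adjusted over the list alone; camera adjusted p = 4.34e-05, adjusted p = 0.154 with an estimated correlation). Of 7 portal fibroblast and mesothelial markers, 3 fell and 0 rose (4 and 0 adjusted over the list alone): Upk3b (120 ± 3.02 to 61.3 ± 2.29 FPKM, log2 change -0.96), Upk1b (-1.06) and Gpm6a (-0.93), with camera adjusted p = 3.77e-06 and adjusted p = 0.0972 with an estimated correlation. Of 27 fibrillar collagen and fibrotic matrix genes, 5 fell and 0 rose (8 fell and 2 rose adjusted over the list alone), among them fibronectin, Fn1 (135 to 87.7 FPKM, log2 change -0.62), and collagen VI, Col6a1 (-0.66) and Col6a2 (-0.57). By fry the contractile, mesothelial and matrix lists passed (adjusted p = 0.0168, 0.000249 and 0.0124). The matrix list had camera adjusted p = 0.0381, and adjusted p = 0.271 with an estimated correlation. Without empty-vector library 1, XPO4 library 0 or XPO4 library 1 it no longer passed (camera adjusted p = 0.0637, 0.0631 and 0.0646), and without XPO4 library 0 the 5 matrix genes were 3.

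Col3a1, collagen III, fell by 0.62 (24.3 to 15.5 FPKM, limma adjusted p = 0.0109), a call that ended without XPO4 library 0 (adjusted p = 0.0546). Col1a1, collagen I (chromosome 11, 94936224 to 94953042), did not pass: it measured 99.1 ± 2.78 FPKM with the empty vector and 78.5 ± 7.66 FPKM with XPO4 (SD, n = 4 and 3; log2 change -0.34, limma adjusted p = 0.0557). Neither did Col1a2 (-0.14), Timp1 (0.27), Ctgf (0.01), Smad7 (0.16) or Tgfb1 (-0.11). Of 30 immediate TGFβ and SMAD targets, 4 rose and 0 fell (5 and 1 adjusted over the list alone), including Cdkn1a. That count was 2 without empty-vector library 0 or XPO4 library 0 or 2, and 1 without XPO4 library 1. The list's median was -0.03, its mean 0.02, and its camera adjusted p 0.968.

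The other large falls at baseline were Evpl, the desmosomal linker envoplakin (chromosome 11, 116220559 to 116238077), which fell from 5.55 ± 1.11 to 0.675 ± 0.0768 FPKM (SD, n = 4 and 3; log2 change -1.95, SE 0.18), and Foxo6 (-1.09), Smpd3 (-1.08) and Gas1 (-1.07). Lgals2 (-1.48, limma adjusted p = 0.0265) and Ydjc (-1.32, limma adjusted p = 0.0389) were called with all libraries. Lgals2 lost the call without empty-vector library 1, 2 or 3 (adjusted p = 0.0778, 0.0729 and 0.0751). Ydjc lost it without empty-vector library 0, 1, 2 or 3 (0.101, 0.0994, 0.0854 and 0.0942) and without XPO4 library 0 or 1 (0.112 and 0.136).

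Fatty acid synthesis genes were lower for 3 of 24 members and higher for 0 (7 and 1 adjusted over the list alone), with the stearoyl-CoA desaturases Scd2 (438 ± 21.6 to 284 ± 9.62 FPKM, log2 change -0.62) and Scd1 (-0.51) among them. Whichever library was left out, 2 were lower. The list's camera adjusted p was 0.031, 0.0521 without empty-vector library 3, and adjusted p = 0.154 with an estimated correlation. By fry the list passed (adjusted p = 0.00236). Of 30 nuclear transport receptors 0 were called by limma and 4 were lower at an unadjusted p under 0.05. Their median was -0.07 with camera adjusted p = 0.031, and adjusted p = 0.537 with an estimated correlation and 0.19 by fry. That camera call ended without empty-vector library 2 (0.103) or XPO4 library 2 (0.157). Among the genes of proteins that exportin-4 is known to carry, Smad3 (-0.29), Eif5a (-0.04) and Eif5a2 (-0.26) did not pass, and Sox2 and Sry were listed at 0 in all libraries.

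Across all 11926 genes tested at baseline, 340 rose and 103 fell at an adjusted p under 0.05, and 1813 had an unadjusted p under 0.05. Of the called genes 160 rose and 10 fell by more than 2-fold. The total of 443 became 276 without XPO4 library 0 and 289 without XPO4 library 1, and the 340 higher genes became 224 without XPO4 library 0. The 103 lower genes became 51, 50 and 54 without empty-vector library 0, 1 and 3, and 52, 46 and 57 without XPO4 library 0, 1 and 2. A block by library set, the replicates 0 and 1 against 2 and 3 in the order of the library codes, gave 63 lower genes. A block by replicate number gave fewer still and ended the baseline calls of Xpo4, Tagln and Col6a1 (values in the section on processing). In 1928 genes (16.2%) the 2 groups did not overlap, against 5.71% by chance.

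**Figure D2:**
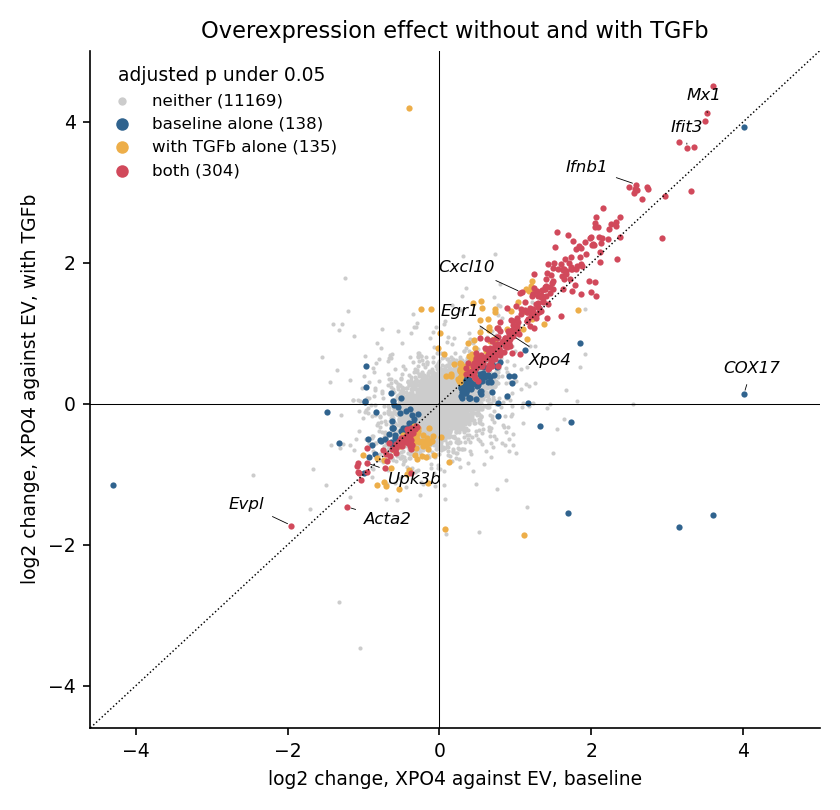
Log2 change with XPO4 against empty vector for each gene tested in both treatments, at baseline (horizontal axis) and with TGFβ (vertical axis); the dotted line marks equal changes. Colours give the genes with an adjusted p under 0.05 at baseline alone (138), with TGFβ alone (135), in both (304) or in neither (11169). Of the genes called in both treatments, 256 were higher and 48 lower in both.

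With TGFβ present, overexpression again came with higher interferon-stimulated genes. Of 47 measured members 46 rose and 0 fell (47 and 0 adjusted over the list alone), with a median log2 change of 1.65. Mx1 rose from 2.15 ± 1.16 to 51.7 ± 5.39 FPKM (SD, n = 4 each; log2 change 4.13, SE 0.23), Ifit3 from 101 ± 9.99 to 1252 ± 37.6 FPKM (3.63, SE 0.08), and Cmpk2, Igtp and Irf7 by 2.36, 2.13 and 1.92. The list passed camera (adjusted p = 6.83e-101, and adjusted p = 0.00345 with an estimated correlation). Ifnb1 rose from 0.0834 ± 0.167 to 8.51 ± 2.53 FPKM (SD, n = 4 each; log2 change 3.11, SE 0.21, limma adjusted p = 9.26e-06). The other largest rises were Iigp1 (3.72), Ms4a4d (3.07), Mpeg1 (3.05), Tgtp1 (3.05, uncertain because of Tgtp2) and Pyhin1, a member of the interferon-inducible HIN-200 family (3.04).

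Chemokines also rose in the TGFβ-treated cells. Of 26 NF-κB targets and chemokines, 8 rose and 0 fell (8 and 0 adjusted over the list alone), with Ccl7 (16.4 to 84.7 FPKM, log2 change 2.30), Ccl2 (1.98), Cxcl10 (1620 ± 36.0 to 4851 ± 281 FPKM, 1.58) and Ccl5 (1.39). The list passed camera with the preset correlation (adjusted p = 3.32e-10) and with an estimated correlation (adjusted p = 0.00375). Of 36 unfolded protein and stress response genes 6 rose and 0 fell (10 and 0 adjusted over the list alone), including Ddit3 (0.69), Atf3 (0.51) and Chac1 (0.45), with camera adjusted p = 1.03e-06 and adjusted p = 0.118 with an estimated correlation. Of 24 p53 targets 2 rose, Cdkn1a (0.63) and Sesn2 (0.53), and 1 fell, the death receptor gene Fas (-0.78). The p53 list had 5 higher and 1 lower adjusted over the list alone, 4 higher over all genes without XPO4 library 2, camera adjusted p = 0.00097, and adjusted p = 0.0681 with an estimated correlation.

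Acta2 fell from 45.3 ± 3.82 to 15.9 ± 2.69 FPKM with overexpression under TGFβ (SD, n = 4 each; log2 change -1.46, SE 0.12, limma adjusted p = 4.57e-05), and Tagln fell from 205 ± 30.6 to 108 ± 15.3 FPKM (log2 change -0.91). Of 21 contractile genes 3 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 2.26e-06, adjusted p = 0.0921 with an estimated correlation). Whichever library was left out, 2 contractile genes fell. The mesothelial markers Upk3b (-0.84) and Upk1b (-0.98) fell, 2 of 7 measured with 0 higher (4 lower adjusted over the list alone; camera adjusted p = 1.18e-06, and adjusted p = 0.0143 with an estimated correlation). Col6a2 (-0.63) and Col6a1 (-0.55) were the 2 of 28 matrix genes that fell, and 0 rose (5 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.187 with an estimated correlation). Of 11 basement membrane genes 3 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.01, adjusted p = 0.108 with an estimated correlation). The 3 lower genes became 0 without empty-vector library 0 or 3 or XPO4 library 0, and 1 without empty-vector library 1 or XPO4 library 1 or 2. The 1 higher gene became 0 without any of the libraries except empty-vector library 2 and XPO4 library 1.

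Of 24 fatty acid genes 3 fell and 0 rose with overexpression under TGFβ (6 and 3 adjusted over the list alone), Scd2 by 0.64 among them, with camera adjusted p = 0.00737 and adjusted p = 0.0681 with an estimated correlation; 1 fell without empty-vector library 1. Of 30 SMAD targets 3 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.11, camera adjusted p = 0.00195, and adjusted p = 0.0484 with an estimated correlation, a call that ended when any of the 8 libraries was left out (0.0835, 0.0615, 0.0834 and 0.0663 without empty-vector library 0 to 3, and 0.095, 0.0625, 0.0841 and 0.0708 without XPO4 library 0 to 3). Of these 3, only 1 rose when any library but empty-vector library 2 or XPO4 library 2 was left out. Col1a1 (164.8 ± 7.94 and 139 ± 8.39 FPKM; SD, n = 4 each; log2 change -0.24), Col1a2 (-0.16), Col3a1 (-0.35), Fn1 (-0.57), Timp1 (0.63), Ctgf (0.11), Smad7 (0.38) and Tgfb1 (-0.05) did not pass, nor did Smad3 (-0.31), Eif5a (-0.01) or Eif5a2 (-0.19). The 13 mitochondrially encoded transcripts had a median of -0.26 with 0 called by limma and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00327, adjusted p = 0.427 with an estimated correlation). They made up 4.03 ± 0.428% of the FPKM in empty-vector and 3.54 ± 0.683% in XPO4 libraries with TGFβ (SD, n = 4 each), and 3.98 ± 0.697% and 3.66 ± 0.291% at baseline (SD, n = 4 and 3).

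Among the largest falls under TGFβ were Evpl (5.92 ± 0.576 to 1.11 ± 0.37 FPKM; SD, n = 4 each; log2 change -1.73), Acta2, Rasl11a (-1.17), Cmtm8 (-1.13), Matn4 (-1.12), Ifi27l1 (-1.09) and Dnajb2 (-1.0). The calls of Cmtm8, Matn4 and Dnajb2 each ended when single libraries were left out. Cmtm8 reached an adjusted p of 0.0755, 0.123, 0.105 and 0.0789 without empty-vector library 0 to 3, and 0.0983 and 0.1 without XPO4 library 0 and 3. Matn4 reached 0.0544, 0.061 and 0.0621 without empty-vector library 0, 1 and 3. Dnajb2 reached 0.111, 0.123 and 0.106 without empty-vector library 0, 1 and 3, and 0.0779, 0.0747, 0.0888 and 0.111 without XPO4 library 0 to 3.

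Across 11976 genes tested under TGFβ, 346 rose and 102 fell, 191 and 11 of them by more than 2-fold, and 1676 had an unadjusted p under 0.05. The 102 lower genes became 60, 56 and 54 without empty-vector library 0, 1 and 3, and 61 and 62 without XPO4 library 0 and 3. With all 4 groups in 1 fit 676 genes were called, 230 of them lower, and on the TPM scale 466, about 1.6e+02 of them lower. In 1227 genes (10.2%) the 2 groups did not overlap, against 2.86% by chance. Across 11746 genes tested in both treatments the overexpression effects had Pearson r = 0.66 and Spearman rho = 0.52, a relation across genes, which are not independent replicates. Of the genes called, 256 were higher in both treatments (9.75 by chance), 48 were lower in both (0.886 by chance) and 0 were called in opposite directions.

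Whether the overexpression effect differed with TGFβ was tested as an interaction over all 15 libraries. Limma called 0 of 11951 genes, and 344 had an unadjusted p under 0.05, fewer than the share of 0.05 of genes that chance gives. The count became 1 without XPO4 library 1 at baseline, empty-vector library 1 with TGFβ or empty-vector library 2 with TGFβ, and on the TPM scale. Among the genes with the smallest p were Cxcl10 (difference of log2 changes 0.50, limma adjusted p = 0.248), Trafd1 (0.51), Cdc26 (0.58), Dhx58 (0.55) and Gtdc1 (1.0) above 0, and BC042782 (-1.65), Cdc42ep2 (-0.60), Slco4a1 (-0.77) and Lrsam1 (-1.18) below 0. Acta2 (-0.25), Col1a1 (0.10), Col1a2 (-0.02), Col3a1 (0.27), Timp1 (0.36), Ctgf (0.10), Smad7 (0.22), Tgfb1 (0.06), Xpo4 (0.00), Smad3 (-0.02), Eif5a (0.03) and Eif5a2 (0.06) did not pass either.

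As sets, 3 lists had a larger overexpression effect under TGFβ by camera. Interferon-stimulated genes had a median difference of 0.23 with 45 of 47 members above 0 (camera adjusted p = 2.35e-17, adjusted p = 0.0551 with an estimated correlation). Immediate SMAD targets had a median of 0.13 with 22 of 30 above 0 (camera adjusted p = 0.00122, adjusted p = 0.0576 with an estimated correlation), and NF-κB targets and chemokines a median of 0.06 with 17 of 26 above 0 (camera adjusted p = 0.0362, adjusted p = 0.269 with an estimated correlation). The other lists had a camera adjusted p of at least 0.0872 in the main fit. Of these, the stress list passed with a block by library set (0.0306), at baseline without empty-vector library 2 (0.00585) or XPO4 library 0 (0.031), and with TGFβ without empty-vector library 0 (0.00668) or XPO4 library 0 or 2 (0.021 and 0.00898). The mitochondrial list passed without empty-vector library 0 or 2 at baseline (0.0209 and 0.0111) and without empty-vector library 3 or XPO4 library 2 with TGFβ (0.00408 and 0.00898). The hypoxia list passed without empty-vector library 0 at baseline (0.0485) or with TGFβ (0.0164), the ribosomal list without empty-vector library 0 or XPO4 library 2 with TGFβ (0.0415 and 0.00873), and the p53 list without XPO4 library 2 at baseline (0.0373). With an estimated correlation each of these left-out fits had an adjusted p of at least 0.231. Without XPO4 library 0 at baseline the 3 lists had an adjusted p of 0.0373, 0.0175 and 0.0208 with an estimated correlation, and the interferon list 0.000148 without empty-vector library 2 with TGFβ. By fry the adjusted p of the 3 lists was 0.0755, 0.0755 and 0.308, so none of the 3 passed. In the interferon list 0 members were called over all genes, 1 was adjusted over the list alone and 11 had an unadjusted p under 0.05. The NF-κB call ended at baseline without empty-vector library 1 or 2 (0.094 and 0.0713) or XPO4 library 1 or 2 (0.168 and 0.185), and with TGFβ without empty-vector library 3 (0.0851) or XPO4 library 2 or 3 (0.115 and 0.0753).

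The TGFβ response itself compares libraries from the separate tables, so it rests on both tables having the same scale; the median log2(FPKM + 1) of a library was 3.89 to 3.96 over both. In empty-vector cells TGFβ came with higher matrix and contractile genes. Of 28 matrix genes 13 rose and 0 fell (16 and 1 adjusted over the list alone), among them Thbs1, thrombospondin-1 (14.9 ± 1.07 to 39.0 ± 3.50 FPKM; SD, n = 4 each; log2 change 1.33), Col11a1 (1.59), Col5a2 (0.64) and Col1a1 (99.1 to 164.8 FPKM, 0.73). Of 21 contractile genes 4 rose and 0 fell (11 and 0 adjusted over the list alone), with Acta2 (19.8 to 45.3 FPKM, log2 change 1.16), Tagln (0.99) and Tpm1 (0.53). Of 30 SMAD targets 6 rose and 0 fell (10 and 1 adjusted over the list alone), including Ctgf (0.68), Sphk1 (0.92) and Pmepa1 (0.63). The 3 lists passed camera (adjusted p = 2.65e-22, 1.07e-11 and 1.07e-11) and did so with an estimated correlation (adjusted p = 0.000196, 0.00682 and 0.000548). Col1a2 rose by 0.66 (limma adjusted p = 0.0297), a call that ended without empty-vector library 1 or 3 with TGFβ (0.0938 and 0.103) and without empty-vector library 0, 2 or 3 at baseline (0.051, 0.0855 and 0.088). Col3a1 (0.14), Timp1 (-0.65), Smad7 (0.15) and Tgfb1 (0.09) did not pass, nor did Xpo4 (-0.10), Smad3 (-0.10), Eif5a (-0.24) and Eif5a2 (-0.06).

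The largest rises with TGFβ in empty-vector cells were Ctsw, cathepsin W (0.152 ± 0.102 to 6.01 ± 1.21 FPKM; SD, n = 4 each; log2 change 2.59), Postn, periostin (1.61), Col11a1, Adam12 (1.45), Thbs1, Crispld2 (1.32), Ctla2a (1.27) and Adamtsl3 (1.23). The largest falls were Rab3b (-1.19), P2rx3 (-1.11), the alarmin Il33 (-1.11), Srcrb4d (-0.99), Sbsn (-0.97), Itgb7 (-0.80), Ivl (-0.77) and Abhd10 (-0.75). Adamtsl3 lost its call without empty-vector library 1 with TGFβ (adjusted p = 0.0562). P2rx3 lost it without empty-vector library 1 or 3 with TGFβ (0.0555 and 0.0561) or library 2 at baseline (0.0594). Srcrb4d lost it without empty-vector library 1 or 2 with TGFβ (0.0616 and 0.0599) or library 1 at baseline (0.0518). Abhd10 lost it without empty-vector library 0 to 3 with TGFβ (0.0639, 0.0595, 0.0668 and 0.0586) or library 0, 2 or 3 at baseline (0.0851, 0.0639 and 0.0806). Over 11951 genes, 148 rose and 64 fell, 13 and 5 of them by more than 2-fold, and 1373 had an unadjusted p under 0.05. The total of 212 became 121 and 140 without empty-vector library 0 and 3 at baseline and 108 without empty-vector library 1 with TGFβ. The 148 higher genes became 90 without empty-vector library 0 at baseline and 77 without library 1 with TGFβ. The 64 lower genes became 31, 40, 42 and 38 without empty-vector library 0 to 3 at baseline, and 31 and 36 without library 1 and 3 with TGFβ. With array weights 323 genes were called, 114 of them lower.

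In XPO4 cells TGFβ came with rises of the same kinds of genes. Of 28 matrix genes 11 rose and 0 fell (16 and 0 adjusted over the list alone), with Thbs1 (19.4 ± 0.766 to 48.5 ± 3.70 FPKM; SD, n = 3 and 4; log2 change 1.28), Col1a1 (78.5 to 139 FPKM, 0.82), Col5a2 (0.69) and Bgn (0.65). Of 30 SMAD targets 8 rose and 0 fell (17 and 1 adjusted over the list alone), including Sphk1 (1.17), Pmepa1 (0.85) and Ctgf (0.78). Of 21 contractile genes 4 rose and 0 fell (9 and 1 adjusted over the list alone; 7 higher over all genes without XPO4 library 2 with TGFβ), with Acta2 (8.03 to 15.9 FPKM, 0.91), Tagln (0.80) and Tpm1 (0.55). The matrix, SMAD and contractile lists passed camera (adjusted p = 8.2e-20, 5e-19 and 2.82e-08), and passed it with an estimated correlation (adjusted p = 0.000172, 0.000106 and 0.0318). For the contractile list that last call ended without XPO4 library 1 or 2 at baseline (0.0785 and 0.0658) or library 1 with TGFβ (0.0613). The XPO4 cells with TGFβ thus stood at 15.9 ± 2.69 FPKM of Acta2 and the untreated empty-vector cells at 19.8 ± 1.22 FPKM (SD, n = 4 each). Col1a2 (0.64), Col3a1 (0.41), Timp1 (-0.29), Smad7 (0.36), Tgfb1 (0.15), Xpo4 (-0.09), Smad3 (-0.12), Eif5a (-0.21) and Eif5a2 (0.00) did not pass.

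The largest rises with TGFβ in XPO4 cells were Ctsw (0.137 ± 0.118 to 5.54 ± 2.25 FPKM; SD, n = 3 and 4; log2 change 2.46), Adam12 (1.60), Ctla2a (1.57), Col11a1 (1.48), Igfbp7 (1.42), Postn (1.42), Lamb3 (1.37) and Crispld2 (1.31). The largest falls were Rab3b (-1.68), Lrsam1 (-1.24), Sbsn (-1.13), Itgb7 (-0.94), Hs3st1 (-0.92), Igfbp6 (-0.90), Ivl (-0.87) and Il33 (-0.86). Igfbp6 lost its call without XPO4 library 0, 1 or 2 at baseline (adjusted p = 0.0658, 0.107 and 0.0581). Il33 lost it without empty-vector library 0 to 3 at baseline (0.0651, 0.0625, 0.0636 and 0.0659), empty-vector library 1 or 2 with TGFβ (0.0676 and 0.0582), XPO4 library 0 to 2 at baseline (0.168, 0.192 and 0.105) and XPO4 library 0 to 3 with TGFβ (0.0562, 0.105, 0.0598 and 0.103). Over 11951 genes, 142 rose and 69 fell, 26 and 5 of them by more than 2-fold, and 1202 had an unadjusted p under 0.05. The total of 211 became 130 and 118 without XPO4 library 0 and 1 at baseline, and the 142 higher genes became 87 without XPO4 library 1 at baseline. The 69 lower genes became 30, 31 and 43 without XPO4 library 0 to 2 at baseline, and 45 and 44 without XPO4 library 0 and 3 with TGFβ; with array weights they became 110. Across genes the TGFβ effects of empty-vector and XPO4 cells had Pearson r = 0.32 and Spearman rho = 0.40. Of the called genes, 94 were higher in both (1.76 by chance), 31 lower in both (0.37 by chance) and 0 called in opposite directions. Both effects come from 1 fit and compare the same separate tables. The chance values do not allow for this, and a difference between the tables would enter both effects.

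**Figure D3:**
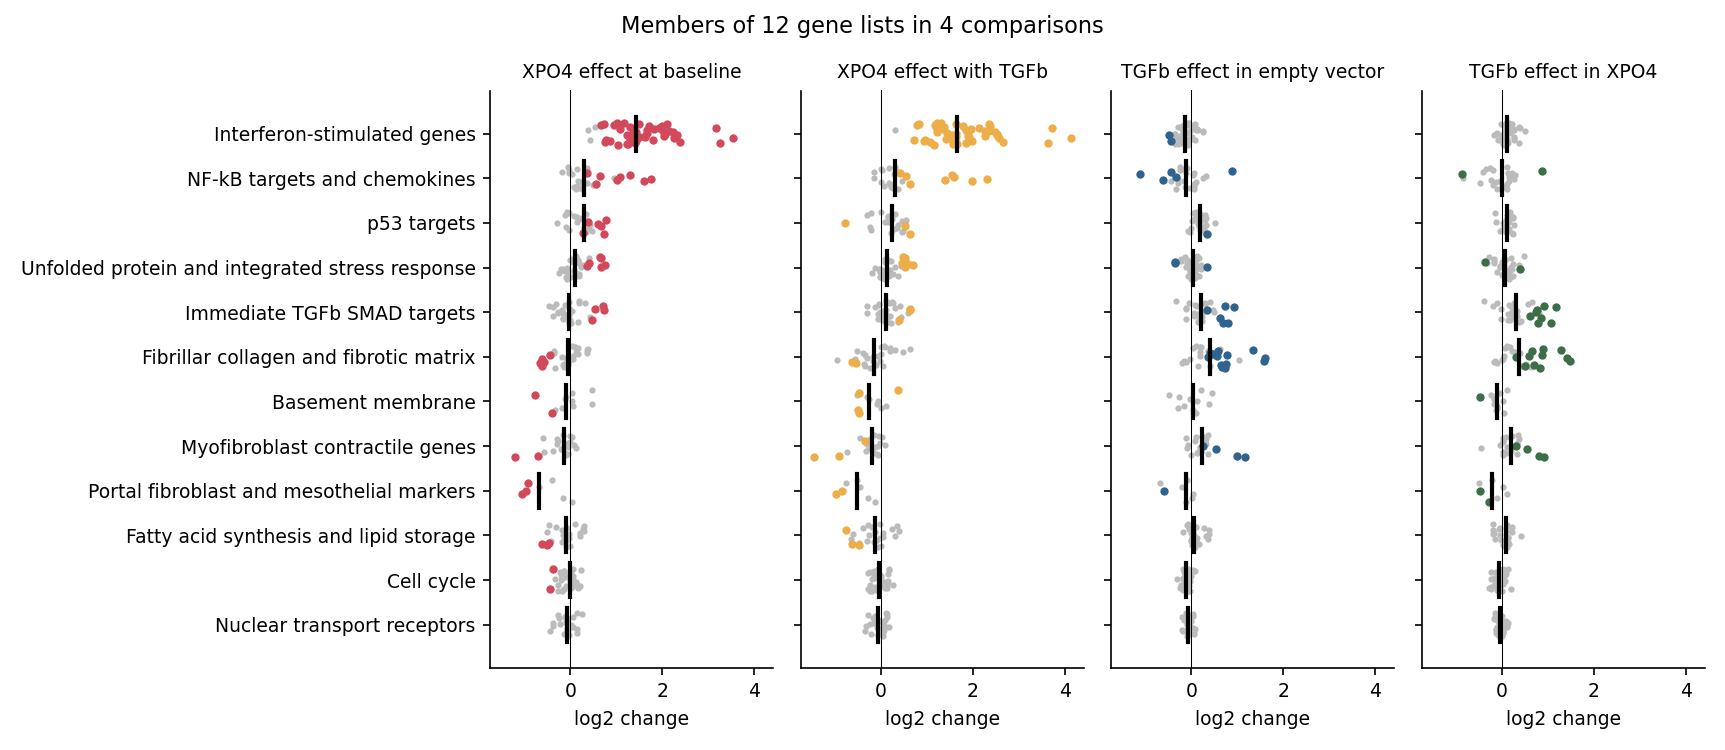
Log2 change (horizontal axes) of each measured member of 12 gene lists in the 4 comparisons of groups. Each dot is 1 gene, coloured where its adjusted p was under 0.05 and grey otherwise, and black bars are list medians. Interferon-stimulated genes had a median of 1.43 and 1.65 with XPO4, and the matrix list one of 0.40 and 0.36 with TGFβ.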

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

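The tests of near-identical copies, both tests of the scaling and the look at the constructs in 1 split of the interaction were chosen after the result was seen. Interferon-stimulated genes were higher with XPO4 in both treatments; the median difference between the treatments was 0.23, which camera called and fry did not, with adjusted p = 0.0551 with an estimated correlation (0.0373 without XPO4 library 0 at baseline and 0.000148 without empty-vector library 2 with TGFβ). Genes with no near-identical copy (15 tested) had a median log2 change of at least 1.37, which argues against reads shared between copies, and the list's lowest median after median centring or quantile normalization was 1.402, which argues against the scaling of the libraries. The change in the summed level of 6 abundant macrophage transcripts was -0.62 FPKM with TGFβ and -0.83 FPKM at baseline, while Isg15 rose from 1087 to 2223 FPKM at baseline, which argues against macrophages in the XPO4 cultures. A dose effect of Xpo4 within groups stayed open (Pearson r = 0.51, permutation p = 0.238; Spearman rho = 0.39, permutation p = 0.236; r = 0.55 without the 2 libraries farthest from the median; n = 15). An effect of the construct or its preparation, with 1 construct per group, cannot be separated from Xpo4 itself, and a response to Xpo4 is a hypothesis.

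Acta2, Upk1b and Upk3b were lower with XPO4 in both treatments. Their highest adjusted p after median centring or quantile normalization was 0.000971, which argues against the scaling. A lower share of mesothelial or epithelial-like cells may explain part of the fall. The 6 other tested members of those lists had a median log2 change of -0.38 with TGFβ (95% interval of the resampled median -0.60 to -0.21) and -0.15 at baseline (-0.55 to 0.10), short of the falls of Upk1b (-0.98 and -1.06), and too few to settle it.

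Chance was tested by regrouping the libraries. At baseline 1 of 35 splits, the real one, called as many as 443 genes, and the highest other called 2. With TGFβ it was 1 of 35 splits, with 448 genes and 3. The TGFβ effect gave 1 of 35 splits in empty-vector cells (212 genes, highest other 1) and 1 of 35 in XPO4 cells (211 genes, highest other 2). For these 4 counts the real split ranked first, the best rank that 35 splits allow. The other splits mix the real groups, which can lower their counts, so the test does not exclude chance. For the interaction the real count was 0, so 100 of 100 splits called at least as many and this count decides nothing about chance. The highest other called 232; it kept the construct of 5 of 7 baseline libraries and of 0 of 8 with TGFβ, so the overexpression effect itself entered its contrast, and 96 of the 100 splits called 0.

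The SMAD targets (median difference 0.13) and the NF-κB targets and chemokines (0.064) also differed between treatments by camera; neither passed by fry or with an estimated correlation (adjusted p = 0.0576 and 0.269, or 0.0175 and 0.0208 without XPO4 library 0 at baseline). The NF-κB call by camera ended at baseline without empty-vector library 1 or 2 (0.094 and 0.0713) or XPO4 library 1 or 2 (0.168 and 0.185), and with TGFβ without empty-vector library 3 (0.0851) or XPO4 library 2 or 3 (0.115 and 0.0753). In single libraries, 21 of 303 groups of 4 held a value far from the other 3, where about 1 in 20 groups would by chance. With the empty vector at baseline these were Matn4 at 2.79 FPKM in library 1, Col6a2 at 48.8, Pmepa1 at 83.0 and Eif5a at 1223 FPKM in library 2, and Ctsw at 0 and Adamtsl3 at 0.539 FPKM in library 3. With the empty vector and TGFβ they were Hs3st1 at 15.8 FPKM in library 0, Ccl5 at 117 and COX17 at 6.70 FPKM in library 1, Ccl7 at 19.4 and Ifnb1 at 0.334 FPKM in library 2, and Col6a2 at 55.7 FPKM in library 3. With XPO4 and TGFβ they were Rasl11a at 1.96, Ccl7 at 71.8 and COX17 at 10.02 FPKM in library 0, Mmp14 at 84.4 and Ifi27l1 at 27.5 FPKM in library 1, Igfbp7 at 77.5 and Pmepa1 at 135 FPKM in library 2, and Col6a1 at 42.6 and Ctgf at 1152 FPKM in library 3.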

How the results depend on the processing

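Median centring was chosen after the data had been seen. Under the alternatives there were 4934 values of 215 named results. Of these, 4721 kept their direction and their side of the threshold, 126 lost the call, 34 gained it and 53 changed sign. None of the results that changed sign, each a gene in 1 comparison, had been called with all libraries. The cause of the changes below was not tested. The labels do not state that replicate numbers pair the libraries, and the main tests did not pair them. Of 21 same-numbered pairs, 3 had deviations with r over 0.1 (range -0.15 to 0.29). In 13 of the 21 pairs a library was closest to its own number among the 3 or 4 of the other group. Chance would give about 1 in 3 or 1 in 4. Between groups, deviations had a mean r of 0.031 within a library set and -0.031 across sets. These hints come from the data and not the design. Pairing or a shared batch is not excluded, and the main tests allow for neither. With the replicate number as a block the baseline count was 224 (205 higher, 19 lower) and Xpo4 changed by 0.87 (adjusted p = 0.0891), while the other counts stayed within 1.5 times. The block leaves the small baseline fit fewer residual degrees of freedom. Empty-vector library 3 at baseline has no XPO4 library of its number and no longer informs that contrast. Calls lost there can therefore reflect lower power and not a smaller change. Among named results it ended 14 calls, including Tagln and Col6a1 at baseline, and gave 4. The fatty acid list at baseline (adjusted p = 0.0509) and the TGFβ pathway list in XPO4 cells (0.0578) lost the call, and the basement membrane list gained it for the interaction (0.0443). A block by library set gave 63 lower genes at baseline, and the unfolded protein and stress list gained the call for the interaction (0.0306) and for TGFβ in XPO4 cells (0.0214). With quantile normalization the list calls gained were ribosomal proteins (0.0247), cell cycle (0.0431) and cholesterol synthesis (0.0416) at baseline, ribosomal proteins (0.0322) and nuclear transport receptors (0.044) with XPO4 and TGFβ, and the stress list for TGFβ in XPO4 cells (0.0252). On the TPM scale 466 genes changed with XPO4 and TGFβ, 311 higher and about 1.6e+02 lower, and the interaction called 1 gene (1 higher). With all 4 groups in 1 fit the count with TGFβ was 676 (230 lower). With array weights TGFβ gave 323 genes in empty-vector cells (114 lower) and 110 lower in XPO4 cells. With an estimated correlation the lists passing were 1, 4, 0, 11 and 4 for overexpression at baseline, with TGFβ, the interaction, and TGFβ in empty-vector and XPO4 cells, and fry called 0 for the interaction. For overexpression with TGFβ, fry called the stress, p53, contractile and matrix lists (adjusted p = 0.00703, 0.0041, 0.00589 and 0.0228). It also called the basement membrane and fatty acid lists (0.00911 and 0.00163). Matrix proteases (0.0192) and heat shock (0.00703) passed by fry and not by camera, and the mitochondrial list did not pass by fry (0.214). The agreement r of the overexpression effects was 0.78 at 5 FPKM or more and 0.53 with a pseudocount of 0.1.

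Sign changes of values near 0 were as follows. Ctgf at baseline was -0.024 with quantile normalization, -0.036 on the TPM scale, -0.00034 with the set block and -0.0069 with median centring. With array weights and TGFβ, Tgfb1 was 0.0055 and Eif5a 0.0082. For the interaction Eif5a was -0.033 with quantile normalization, Eif5a2 -0.042 with array weights, and Xpo4 -0.00019 on the TPM scale, -0.018 with the set block and -0.050 with array weights. For TGFβ in XPO4 cells Eif5a2 was -0.0034 with a pseudocount of 0.1, -0.0048 with quantile normalization, -0.014 with the set block and -0.074 with array weights.

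Leaving out 1 library at a time, the baseline count ranged from 276 to 451 (224 to 346 higher, 46 to 105 lower), the lower genes with TGFβ from 54 to 92, and the interaction from 0 to 1 (0 to 1 higher, 0 to 1 lower). The TGFβ count was 108 to 243 in empty-vector cells (77 to about 1.7e+02 higher, 31 to 78 lower) and 118 to 214 in XPO4 cells (87 to 147 higher, 30 to 73 lower). At baseline Ctgf was -0.023 to 0.034, and with TGFβ Tgfb1 was -0.098 to 0.017 and Eif5a -0.057 to 0.044. For the interaction Xpo4 was -0.17 to 0.10, Col1a2 -0.13 to 0.10, Smad3 -0.073 to 0.036, Eif5a2 -0.11 to 0.19 and Eif5a -0.020 to 0.081. For TGFβ in empty-vector cells Tgfb1 was -0.0078 to 0.14, Xpo4 -0.20 to 0.077 and Eif5a2 -0.19 to 0.045, and in XPO4 cells Eif5a2 was -0.18 to 0.13.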

Other observations

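The test of genes raised by TGFβ below was planned before its result was seen; the genes named as examples in it were chosen afterwards, as were Isg15 and Ifna4. XPO4 overexpression moved few genes in the other lists fixed beforehand. Egr1, an immediate early transcription factor, rose from 52.96 ± 1.43 to 95.01 ± 3.02 FPKM at baseline (SD, n = 4 and 3; log2 change 0.83) and from 37.7 ± 2.90 to 70.5 ± 5.50 FPKM with TGFβ (SD, n = 4 each; 0.89). It was 1 of 2 SRF and MRTF targets of 19 that rose at baseline while 2 fell (camera adjusted p = 0.968). With TGFβ 1 rose and 3 fell (0.852), and 2 rose without empty-vector library 0 or XPO4 library 2. Of 19 YAP and TAZ targets 2 rose at baseline (camera adjusted p = 0.394) and 0 when any library was left out. With TGFβ limma called 0 and 6 had an unadjusted p under 0.05.

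Of 39 cell cycle genes 2 fell at baseline with camera adjusted p = 0.102. They became 1 without empty-vector library 2 or XPO4 library 2 and 0 without any other, and the list had camera adjusted p = 0.0398 without XPO4 library 0 (adjusted p = 0.188 with an estimated correlation). Basement membrane genes fell for 2 of 11 at baseline (0.153), and for 1 without empty-vector library 0, 1 or 3 or XPO4 library 1 or 2. Of 22 cholesterol synthesis genes 1 fell at baseline (0.096), and 0 without empty-vector library 0, 1 or 3 or XPO4 library 0 or 1. By fry the basement membrane and cholesterol lists passed at baseline (adjusted p = 0.0129 and 0.00332), and the cell cycle list did not (0.0588). With TGFβ 1 of the 22 cholesterol genes fell and 0 rose, and their list passed camera (adjusted p = 0.0348, adjusted p = 0.108 with an estimated correlation). That call ended without empty-vector library 1 or 2 (0.0521 and 0.087) or XPO4 library 0 or 3 (0.0564 and 0.103), and 0 fell without any library but XPO4 library 1. Limma called 0 of 49 ribosomal protein genes, 0 of 31 translation factors, 0 of 13 mitochondrial transcripts, 0 of 27 TGFβ pathway components and 0 of 7 quiescent stellate cell genes at baseline, with 0, 3, 0, 7 and 0 of them at an unadjusted p under 0.05 and camera adjusted p of 0.394, 0.813, 0.301, 0.173 and 0.968. The ribosomal list passed without empty-vector library 2 (0.0219; adjusted p = 0.539 with an estimated correlation), the mitochondrial list without empty-vector library 1 (0.0329; adjusted p = 0.43 with an estimated correlation), and 1 pathway component was called without empty-vector library 3. With quantile normalization the ribosomal, cell cycle and cholesterol lists passed camera at baseline (0.0247, 0.0431 and 0.0416). BMP targets, matrix proteases, hypoxia, NRF2 and heat shock lists had camera adjusted p between 0.968 and 0.969 at baseline. Markers of other liver cells were mostly under 1 FPKM: 2 of 20 hepatocyte, 3 of 17 macrophage, 3 of 15 endothelial and 3 of 12 cholangiocyte markers could be tested. Limma called 0 of them with overexpression at baseline or with TGFβ, with 3 and 4 at an unadjusted p under 0.05.

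Interferon genes themselves were low. Of 16 listed, 3 reached 1 FPKM in any library, and Ifng was listed at 0 throughout. Ifna4, whose near-identical relatives make its level uncertain, was listed at 0 in the 8 empty-vector libraries and had a mean of 2.19 FPKM in the XPO4 group at baseline and 3.05 FPKM with TGFβ. Isg15 stood at 1087 ± 101 FPKM in empty-vector cells at baseline (SD, n = 4), rank 37 of 38277 genes, and Cxcl10 ranked 14. These genes were thus abundant in cells with the empty vector. Cells without any vector were not measured.

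TGFβ came with set calls in several of the same lists in empty-vector cells. Of 26 NF-κB targets and chemokines 4 fell and 1 rose, with Ccl5 (207 ± 12.1 to 135 ± 12.6 FPKM; SD, n = 4 each; log2 change -0.61) and Cxcl10 (-0.34) lower and Ptgs2, the inducible cyclooxygenase, higher (0.88; camera adjusted p = 0.0089, adjusted p = 0.107 with an estimated correlation, 0.0273 without XPO4 library 0 at baseline). Of 47 interferon-stimulated genes 2 fell and 0 rose (camera adjusted p = 0.000231, adjusted p = 0.165 with an estimated correlation), 1 without empty-vector library 0 or 1 at baseline and 4 without empty-vector library 2 with TGFβ, where adjusted p = 0.00534 with an estimated correlation. In XPO4 cells limma called 0 of these 47, 7 were higher at an unadjusted p under 0.05, and the median was 0.11 (camera adjusted p = 5.59e-05, adjusted p = 0.134 with an estimated correlation); 1 was called without empty-vector library 2 at baseline, and without empty-vector library 2 with TGFβ adjusted p = 0.0193 with an estimated correlation. Cell cycle genes had a median of -0.11 with TGFβ in empty-vector cells, with 0 of 39 called by limma and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.000146, and adjusted p = 0.00418 with an estimated correlation). In XPO4 cells 0 of the 39 were called by limma and 1 was lower at an unadjusted p under 0.05 (camera adjusted p = 0.0595, adjusted p = 0.082 with an estimated correlation; camera 0.0408 and 0.0467 without XPO4 library 1 at baseline and with TGFβ, with adjusted p = 0.0789 and 0.0823 with an estimated correlation). Of 19 matrix proteases and inhibitors 2 rose with TGFβ in empty-vector cells, Mmp14 (0.55) and Mmp2 (0.48), and 1 fell, Mmp13 (-0.61; camera adjusted p = 0.0748, adjusted p = 0.107 with an estimated correlation). Mmp13 lost its call without empty-vector library 0 or 2 at baseline (0.051 and 0.0614) or 0, 1 or 3 with TGFβ (0.0579, 0.0661 and 0.0586), where 0 fell; 2 fell without empty-vector library 1 at baseline or XPO4 library 2 with TGFβ. Upk3b (-0.59) was lower. Egr1 (-0.48) was the 1 SRF and MRTF target that fell, while 3 rose. That list had camera adjusted p = 0.000158, and 0.0868 with an estimated correlation (0.0421 without empty-vector library 2 with TGFβ). Ribosomal, hypoxia and nuclear transport lists passed camera downward with 0 genes called by limma (adjusted p = 9.73e-05, 0.00905 and 0.0143). With an estimated correlation they did not pass (0.285, 0.263 and 0.232), and the last 2 lost the camera call in 3 and 2 left-out fits.

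Of the lists tested for TGFβ in empty-vector cells, 7 more passed camera with both correlations. Of 24 p53 targets 1 rose, Cdkn1a (0.33), and 0 fell (camera adjusted p = 6.92e-07, and adjusted p = 0.00849 with an estimated correlation). Cdkn1a lost its call without empty-vector library 0 to 3 at baseline (0.0505, 0.0641, 0.0883 and 0.0615) or 0 to 2 with TGFβ (0.0869, 0.102 and 0.0709), and with no intensity trend (0.0643). The count was 0 in 6 of these 7 left-out fits, 1 without empty-vector library 1 at baseline, where another member was called, and 2 without XPO4 library 2 of either treatment. Of 22 cholesterol synthesis genes 1 rose and 0 fell (camera adjusted p = 0.00545, and adjusted p = 0.0228 with an estimated correlation), and 0 rose without empty-vector library 0, 2 or 3 at baseline or 0, 1 or 2 with TGFβ, or XPO4 library 0, 1 or 2 at baseline or 0 with TGFβ. Fatty acid genes had a median of 0.05 with 0 of 24 called by limma and 3 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0155, and adjusted p = 0.0367 with an estimated correlation). The second call ended without empty-vector library 0 or 2 at baseline (0.0508 and 0.0581) or 0 or 2 with TGFβ (0.0882 and 0.0583), and 1 gene was called without empty-vector library 3 at baseline. Of 7 mesothelial markers 1 fell, Upk3b, and 0 rose (camera adjusted p = 0.00508, and adjusted p = 0.0243 with an estimated correlation, 0.0548 without empty-vector library 2 at baseline); 2 fell without empty-vector or XPO4 library 2 with TGFβ. In XPO4 cells 2 of the 7 fell and 0 rose (camera adjusted p = 0.00257, and adjusted p = 0.0359 with an estimated correlation), and 1 fell without XPO4 library 0, 1 or 2 at baseline or 0 or 3 with TGFβ. The call with an estimated correlation ended without XPO4 library 1 or 2 at baseline (0.0785 and 0.0737) or 0, 1 or 2 with TGFβ (0.0681, 0.0613 and 0.099). Of 19 YAP and TAZ targets 2 rose and 0 fell (camera adjusted p = 0.000619, and adjusted p = 0.0228 with an estimated correlation, 0.0541 without empty-vector library 2 at baseline). Of these 2, 1 rose without empty-vector library 0 to 3 at baseline or 0 or 1 with TGFβ, or XPO4 library 2 at baseline or 0 or 3 with TGFβ. Translation factors (median -0.09) and heat shock proteins (-0.12) had 0 of 31 and 0 of 16 called by limma and 3 and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.000231 and 0.00407, and adjusted p = 0.0228 and 0.0228 with an estimated correlation). In XPO4 cells none of these other 6 lists passed with both correlations. The p53 list (0 of 24 called by limma, 4 higher at an unadjusted p under 0.05), the cholesterol list (0 of 22, 3 higher), the YAP and TAZ list (2 of 19 higher) and the translation factors (0 of 31, 2 lower) had camera adjusted p = 0.00257, 0.019, 0.0253 and 0.000937, and adjusted p = 0.0792, 0.0564, 0.119 and 0.0523 with an estimated correlation. The fatty acid list (0 of 24 called by limma, 3 higher at an unadjusted p under 0.05) and the heat shock list (0 of 16, 1 lower) both had camera adjusted p = 0.112. The p53 call ended without XPO4 library 2 at baseline (0.0672), and the YAP and TAZ call without XPO4 library 2 at baseline (0.0741) or 0 with TGFβ (0.0639), with 1 higher without XPO4 library 0 or 2 at baseline. In the cholesterol list 1 gene was called without XPO4 library 1 with TGFβ, and in the fatty acid list 1 without empty-vector library 3 at baseline or 0 with TGFβ. With an estimated correlation the cholesterol list passed without XPO4 library 3 with TGFβ (0.0417), and the translation factors without empty-vector library 0 or 1 at baseline (0.0481 and 0.0475) or 0 or 3 with TGFβ (0.036 and 0.0413).

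A planned test asked whether overexpression opposes the TGFβ response across genes. The 94 genes raised by TGFβ in both vector groups had a median main effect of overexpression of -0.11 (95% interval of the resampled median -0.16 to -0.05). Of these, 22 were lower and 8 higher with XPO4, where the shares over all tested genes would give 4.29 and 5.67. Acta2 (-1.34), Tagln (-0.81) and Gpc1, a cell-surface proteoglycan (-0.57), were lower, and Has2, a hyaluronan synthase (0.63), was higher. The 31 genes lowered by TGFβ had a median of 0.09 (-0.05 to 0.16). Of them 9 were higher and 5 lower, where those shares would give 1.87 and 1.41. Both main effects come from the same 15 libraries, which the shares do not allow for. Across 11951 genes they had Pearson r = -0.064 and covariance -0.0044, against -0.079 and -0.0018 in 100 simulations with no change. The median of the raised genes lay between the values set beforehand for and against opposition, and its interval reaches beyond -0.1, so the question stays open.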
